A study of Rattus norvegicus with 6 samples.

How the data were processed

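The data are the deposited value table of 6 Affymetrix Rat230_2 arrays of liver RNA, with 31099 probe sets, and the instrument settings of each array. The deposited values are on a log2 scale. Per the submitters' processing notes, R 2.0.1 and the affy package 1.5.8 were used, and both RMA and GCRMA are named. Which of these made the table is not given in the sources used here. The values have a dense floor near 2 to 3, and differences between low values are compressed there. No scanner intensities were used here. Arrays give no counting depth, and their number limits the precision.

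Groups were taken from the labels: vehicle at 6 h (1 array of RNA pooled from 2 rats), TA at 6 h (2 arrays of 1 animal each), vehicle at 24 h (1 pooled array) and TA at 24 h (2 arrays). A pool averages its animals, and its error could not be estimated, so that standard errors assume that a vehicle array varies like a treated one. Fluidics runs were inferred from the staining times in the array settings. These put the vehicle pool of 6 h and TA_6h animal 1 in a first run and the 4 other arrays in a second. All arrays of the 24 h comparison were thus in 1 run, and the 6 h comparison spanned both.

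The 57 control probe sets were left out. The platform annotation, which can be old, pairs 20826 probe sets with 1 gene symbol, 436 with several and 9780 with none. Symbols were looked up in the reference table by gene identifier for 20764 of them, and 0 changed. Probe sets with several symbols were not named. Probe sets whose mean over the 6 arrays lay above the 40th percentile (2.82) were kept, 18625 in all. A gene with several probe sets was represented by the one with the highest mean, which left 10449 genes for the list tests.

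Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 2 residual and 1.60 prior degrees of freedom. Contrasts were TA against vehicle at 6 h and at 24 h, their mean, their difference, and TA at 24 h against TA at 6 h. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05, all two-sided. Limma's p-values for single probe sets measure the spread between animals of the treated groups. Camera, used below for gene lists, compares the genes of a list with all other genes on the same arrays. At a preset correlation its p-values treat genes as the replicates and do not measure the spread between animals. Its direction is relative to the other genes. Of 34 gene lists fixed before the data were examined, 33 had at least 4 measured genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The list of neutrophil markers had 2 measured genes and was not tested. Camera with an estimated correlation and fry were alternatives.

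Genes were named by a rule fixed at the same time. For each time these were up to 12 each way among genes past the threshold, filled up with the largest differences among genes at least 2-fold apart from the vehicle pool in the same direction in both animals, which are given as values only. For the mean and the difference of the times it was up to 6 each way. In each list, the members past the threshold or else the 2 with the smallest p were named, and 16 genes were always looked up. Of these, Cyp1a1 was below the filter and Cyp2b1 had no probe set with its symbol alone. Asl, Ass1, Aurka, Cdk1, Col1a1, Col1a2, Cry1, Dcn, Hal, Hp, Nr1d1, RT1-Ba, Stat3 and Tat are list members outside this rule, chosen after their values were seen.

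The procedure was tested on simulated arrays of the same size, with variances drawn from the fitted prior, which gave a prior of 1.61 degrees of freedom. Of 50 probe sets changed by 2 on the log2 scale at 6 h, 23 were recovered, of 50 changed by 1, 0, and of 50 changed by 4, 40, among 18625 probe sets. The sets changed by 1, 2, 3 and 4 were in the same run, which eases the adjusted threshold for each. Recovery with fewer large changes was not tested and may be lower. In the same simulation 6 unchanged probe sets were called. A shift of 0.2 in all Nrf2 targets at 6 h was called by camera in 19 of 20 simulations with independent genes among 10449 genes. With an estimated correlation it was called in 0 of 20, at a shift of 0.4 as well. Fry called it in 1 of 20, and in 5 of 20 at a shift of 0.4. Lists of correlated genes were not simulated. The alternatives covered the filter, the prior, the control group, an additive model, normalization, the summary of probe sets, the list test, a replicate block and leaving out arrays. The fluidics run, the vehicle pool of the other time, the 2 reduced lists, the replicate block in the list tests and leaving out animals in the list tests between times were added after seeing the data.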

Results

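Liver RNA of male Sprague Dawley rats given tienilic acid (TA), a uricosuric diuretic withdrawn from use because of hepatitis, was measured on 6 Affymetrix rat arrays. Rats received TA at 100 mg/kg or its vehicle by mouth. Livers were taken 6 h after 1 dose, or at 24 h after doses at 0 and 16 h. Each time had 2 arrays of TA, each from 1 animal, and 1 vehicle array made from RNA of 2 rats pooled, so that 8 animals contributed. The series title poses the question of early gene induction and of a role for danger signals, which the comparisons of TA with vehicle at each time address. The number of arrays limits the precision of every value: the median standard error of a log2 difference was 0.15. The vehicle groups have no replicate. For single probe sets, the error of each comparison rests on the spread between the 2 treated animals of each time, 2 residual degrees of freedom in all. Camera's p-values for gene lists instead compare the genes of a list with all other genes on the same arrays. Both animals of a time were compared with the same pool, so the same direction in both is not independent evidence. Over all probe sets their differences from it correlated at 0.44 at 6 h and 0.39 at 24 h. For the list counts of genes moving in both animals, the share over all genes is not given here. Array medians lay between 3.27 and 3.31 (log2), and correlations between arrays, across probe sets, between 0.984 and 0.994.

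At 6 h, targets of Nrf2, the transcription factor of the antioxidant and electrophile response, rose as a list. The median log2 difference of TA from vehicle over its 25 measured genes was 0.31, 14 of them were higher in both treated animals and 3 lower in both (limma's camera test, adjusted p = 5.2e-05; adjusted p = 0.72 with an estimated correlation). Akr7a3, an aldehyde reductase, had a log2 difference of 1.08 ± 0.14 (SE, n = 2 treated animals), from 11.17 in the vehicle pool to 12.28 and 12.22 in the animals. Srxn1, which reduces overoxidised peroxiredoxins, had 1.22 ± 0.19, Nqo1, a quinone reductase, 0.71 ± 0.15, Txnrd1, thioredoxin reductase, 0.68 ± 0.15 and Gclc, a subunit of the enzyme that begins glutathione synthesis, 0.41 ± 0.10. None of these genes passed limma's test on its own, with adjusted p from 0.73 for Akr7a3 to 0.80 for Gclc. Hmox1, heme oxygenase, was at 8.77 in animal 1 and 10.28 in animal 2, on either side of the vehicle pool at 9.08. Nqo1 and Gclc were also at 11.69 and 10.42 in the vehicle pool of 24 h, so that for these genes the vehicle pool of 6 h was the lowest of the 6 arrays. Srxn1 was at 7.91 in the vehicle pool of 24 h, against a TA mean of 8.62 at 6 h. By the inferred runs, animal 2 was stained in another fluidics run than the vehicle pool and animal 1. Without animal 2 the median of the Nrf2 list was 0.19 and its call was lost. With the run as a block the fit is the same by construction, since animal 2 is the only 6 h array of the second run. That setting is therefore no separate check. Without animal 1 the median was 0.22, still called.

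The other lists called at 6 h were 5, all upward in TA relative to the other genes. The median over all probe sets was -0.02 at 6 h. A call is therefore not a rise of every list in itself: the PPAR alpha list had 17 positive and 15 negative genes. Genes of cholesterol synthesis had a median difference of 0.20 over 20 genes (adjusted p = 0.0055), with 13 higher in both animals. Among them Mvd, a decarboxylase of the mevalonate pathway, had 0.73 ± 0.15 and Msmo1 0.26 ± 0.10. Cell cycle genes had a median of 0.18 over 34 genes (adjusted p = 5.2e-05), with Bub1, a mitotic checkpoint kinase, at 1.15 ± 0.21 and the cyclin Ccnd1 at -1.14 ± 0.20. Markers of Kupffer cells and macrophages had 0.12 over 16 genes (adjusted p = 0.0079), MHC and antigen presentation genes 0.26 over 18 (adjusted p = 0.022), and PPAR alpha targets 0.01 over 32 (adjusted p = 0.042), with Ehhadh and Eci1, enzymes of fatty acid oxidation, at 0.54 ± 0.16 and 0.41 ± 0.10. All 6 calls of 6 h were lost with an estimated correlation (adjusted p = 0.72 for each) and with fry.

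Several of these lists differed between the treated animals, and without animal 1 the lists called were 2 in place of 6. The macrophage and MHC lists had medians of 0.27 and 0.48 in animal 1 but 0.04 and -0.01 in animal 2, and without animal 1 their adjusted p were 0.44 and 0.99. The class II gene RT1-Ba was at 12.91 in animal 1, 10.12 in animal 2 and 10.13 in the vehicle pool, and its other probe set at 8.78, 8.46 and 8.43. Animal 1 also had the highest difference between 3′ and 5′ probe sets of GAPDH, a measure of RNA integrity, at 2.26 (log2), against 1.82 to 2.04 on the other arrays, whereas the same measure for actin, 4.31 in animal 1, lay within the 4.17 to 4.36 of the others. The cell cycle list had a median of 0.05 in animal 1 and 0.26 in animal 2, and lost its call without animal 2 (adjusted p = 0.084). Against the vehicle pool of 24 h in place of that of 6 h, the cell cycle median turned to -0.54 (adjusted p = 2.5e-07), with Bub1 and Ccnd1 at 7.32 and 9.22 in that pool. Against the same pool the MHC and macrophage medians were 0.55 and 0.23, both still called. The MHC list lost its call with quantile normalization (adjusted p = 0.091) and with each array centred on its median (adjusted p = 0.10). Without animal 1 the cholesterol list had a median of 0.10 and lost its call (adjusted p = 0.079), as it did against the vehicle pool of 24 h (0.11, adjusted p = 0.41) and with both pools as 1 control group (0.13, adjusted p = 0.052). The PPAR alpha list lost its call without either animal, with medians of 0.04 without animal 1 and 0.02 without animal 2. Its call was also lost with no filter (adjusted p = 0.056), the mean of probe sets (0.073) and both pools as 1 control group (0.33). Against the vehicle pool of 24 h, where Eci1 was at 12.19, it was lost as well (-0.01, adjusted p = 0.94).

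No probe set passed limma's test at 6 h: 0 of 18625 were called, with a smallest adjusted p of 0.64, and 1087 had an unadjusted p under 0.05 where chance gives 931. Of these 1087, 295 were higher and 792 lower. The cause of this lean was not tested. By size, 43 probe sets were at least 2-fold higher than the vehicle pool in both treated animals and 55 at least 2-fold lower, while 417 differed by 2-fold between the 2 treated animals. With each array centred on its median, the split was 53 higher of 97. In animal 1 alone 469 probe sets passed 2-fold, and in animal 2 alone 265. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 difference of 2.70 ± 0.70 and Cyp8b1, the sterol 12-alpha-hydroxylase, 1.62 ± 0.46. Akr1b7, an aldose reductase family member, had 3.22 ± 1.81, Mst1 4.19 ± 0.34, Clca2 4.35 ± 0.44, Vsig10 1.83 ± 0.23, Shisa3 1.74 ± 0.27 and Mocos, which sulfurates the cofactor of xanthine dehydrogenase, 1.87 ± 0.09. On the other side were the liver transcription factor Onecut1 at -2.57 ± 0.57, Akr1c1 at -2.41 ± 1.34, Hamp, the iron hormone hepcidin, at -1.91 ± 0.91, Tnfrsf12a, the TWEAK receptor, at -1.70 ± 0.16, Slc25a30 at -1.90 ± 0.68 and Sult1c2, a sulfotransferase, at -1.65 ± 0.57. Tfrc, the transferrin receptor, had 1.37 ± 0.17, and Ada, adenosine deaminase, 1.18 ± 0.09, which was called when adjusted over the list alone, 1 of the 14 urate and organic anion genes. Of the 98 probe sets past 2-fold, 14 lay beyond both vehicle pools by as much. Mst1, Clca2 and Mocos stood at 7.39, 2.42 and 5.04 in the vehicle pool of 6 h and at 11.02, 6.67 and 6.63 in that of 24 h, close to the treated animals. Against the pool of 24 h the direction turned for Cyp7a1, at 11.98 there, for Onecut1 at 8.40, for Slc25a30 at 8.73 and for Tfrc at 11.83. Vsig10, Ada and Shisa3 were at 6.85, 6.53 and 4.14 in that pool, nearer to their TA means of 7.21, 6.73 and 5.24 than in the pool of 6 h, and Tnfrsf12a had a difference of -0.53 from it.

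The lists of inflammatory and stress genes were not called at 6 h. Cytokines, chemokines and NF-kB targets had a median of 0.00 over 31 genes (adjusted p = 0.15), acute phase proteins -0.06 over 20 (adjusted p = 0.15), the interferon response 0.00 over 28 (adjusted p = 0.70) and heat shock proteins -0.02 over 19 (adjusted p = 0.92), a median whose sign turned when arrays were rescaled. Camera's direction was upward for the heat shock list and its mean was -0.03. The interferon list had a mean of -0.04 with an upward test. The acute phase list had a mean of -0.28, with 17 of 20 genes negative and 13 lower in both animals. Within the cytokine list Nfkbiz had 0.61 ± 0.13 and Tlr2 0.53 ± 0.10. Immediate early genes had a median of -0.61 in animal 1 and 0.12 in animal 2 (adjusted p = 0.60), and Myc was at 5.48 and 7.60 in these animals with the vehicle pool between them. The p53 targets Cdkn1a and Mdm2 had -0.48 ± 0.17 and 0.18 ± 0.09, with -0.01 on the other probe set of Cdkn1a and -0.30 and -0.04 on those of Mdm2. The P450 genes Cyp2c11 and Cyp2c6v1, of the family that oxidises TA in humans, had -0.28 ± 0.42 and -0.07 ± 0.10, and the PPAR alpha target Cyp4a1 0.51 ± 0.21. Albumin, Alb, was at 16.62 in the vehicle pool and at 16.67 and 16.57 in the animals.

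**Figure D1:**
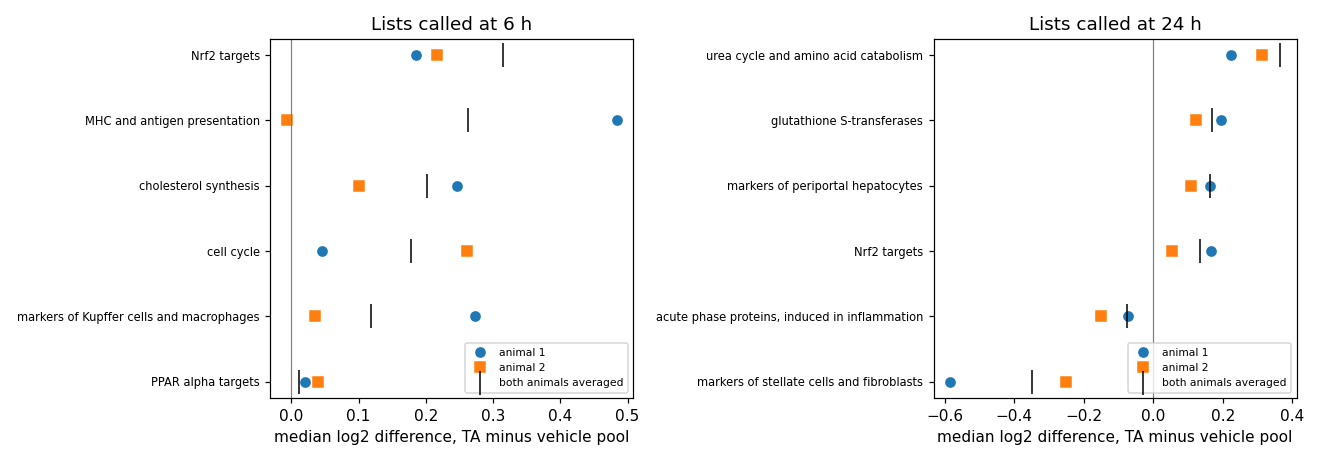
Median log2 difference of TA from the vehicle pool of the same time (x axis) for each gene list called at 6 h (left) and at 24 h (right), with circles for treated animal 1, squares for treated animal 2 and a bar for the median after averaging both animals. The Nrf2 list lies above 0 in both animals at 6 h (0.19 and 0.22), whereas the MHC list lies at 0.48 in animal 1 and -0.01 in animal 2.

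At 24 h, genes of the urea cycle and amino acid catabolism rose as a list, with a median log2 difference of 0.36 over 25 genes, 21 of them higher in both treated animals and 1 lower in both (camera, adjusted p = 1.7e-09; adjusted p = 0.60 with an estimated correlation). Sds, serine dehydratase, had the largest value, 4.08 ± 0.59, from 6.73 in the vehicle pool to 10.94 and 10.68 in the animals. Gls2, liver glutaminase, had 0.58 ± 0.10, Hal, histidine ammonia-lyase, 0.58, Tat, tyrosine aminotransferase, 0.55, and the urea cycle enzymes Asl and Ass1 0.40 and 0.36. Sds was at 10.16 in the vehicle pool of 6 h, so that its value in the vehicle pool of 24 h was the lowest of the 6 arrays. Without TA_24h animal 2 the median of the list was 0.22, still called, and against the vehicle pool of 6 h it was 0.18 (adjusted p = 0.012). Without Sds, it was 0.31 (adjusted p = 2.9e-08), a setting chosen after its value was seen. Periportal hepatocyte markers also rose as a list (median 0.16 over 14 genes, 2 of them called when adjusted over the list alone, adjusted p = 0.0037; adjusted p = 0.77 with an estimated correlation). They share 8 genes with the urea cycle list, and the other 6 had a median of -0.03 (adjusted p = 0.91).

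Glutathione S-transferases rose as a list at 24 h, by a median of 0.17 over 19 genes with 12 higher in both animals (adjusted p = 0.0031; adjusted p = 0.77 with an estimated correlation). Gsta3 had 1.20 ± 0.15 and was called when adjusted over the list alone, and Gstm7 had 0.62 ± 0.18. This list shares 2 measured genes with the Nrf2 list, Gsta3 among them, so the calls of both lists are not separate evidence. The Nrf2 list had a median of 0.13 over 25 genes (adjusted p = 0.043; adjusted p = 0.94 with an estimated correlation), with Akr7a3 at 0.58 ± 0.14, Gclc at 0.24 ± 0.10 and Nqo1 at 0.13 ± 0.15. Without TA_24h animal 1 its median was 0.05 and its call was lost (adjusted p = 0.26), as it was without either animal of 6 h (adjusted p = 0.11). The call was also lost with quantile normalization (adjusted p = 0.13), centring (0.090), the mean of probe sets (0.066) and both pools as 1 control group (0.13). Asl and Akr7a3 were at 12.35 and 11.17 in the vehicle pool of 6 h, above their TA means of 12.21 and 10.88 at 24 h. Against the vehicle pool of 6 h, the medians of the transferase, Nrf2 and periportal lists were -0.03, -0.08 and -0.01, none of them called.

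Markers of stellate cells and fibroblasts fell as a list at 24 h, with a median of -0.35 over 15 genes, 10 of them lower in both animals and 0 higher in both (adjusted p = 0.0029; adjusted p = 0.77 with an estimated correlation). Sparc, a matrix glycoprotein, had -0.61 ± 0.11, and the collagens Col1a1 and Col1a2 -0.57 and -0.64. Decorin, Dcn, had -0.27 in animal 1 and -2.27 in animal 2. Markers of sinusoidal endothelium had a median of -0.13 (adjusted p = 0.28) and those of macrophages 0.03 (adjusted p = 0.95). Without TA_24h animal 2 the stellate median was -0.58, and without animal 1 it was -0.25, both still called. Against the vehicle pool of 6 h it was -0.75 and the call was lost (adjusted p = 0.064). Acute phase proteins also fell as a list, with a median of -0.08 and a mean of -0.27 over 20 genes, 12 lower in both animals. Its adjusted p was 0.0031 with camera, and 0.77 with an estimated correlation. The values of 6 h were alike, with a median of -0.06, a mean of -0.28 and 13 genes lower in both animals. The difference of effects between the times was not called (camera, adjusted p = 0.28). A2m, alpha-2-macroglobulin, had -1.59 ± 0.62, Lbp, the lipopolysaccharide binding protein, -1.04 ± 0.19, Stat3 -0.78 and Serpina3n -0.70 ± 0.21. Haptoglobin, Hp, was at -0.01. Without TA_24h animal 1 the acute phase median was -0.15, still called, and against the vehicle pool of 6 h it was -0.22 (adjusted p = 0.0098).

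In limma's test, 1 of 18625 probe sets was called at 24 h, and 984 had an unadjusted p under 0.05 where chance gives 931. Of these 984, 370 were higher and 614 lower. The called probe set has no gene symbol here and was at 9.84 in the vehicle pool of 24 h and between 2.19 and 2.61 on the 5 other arrays, a log2 difference of -7.61 (limma, adjusted p = 0.0099). Those 5 arrays lay at the compressed floor of the values, so that the test's error for it does not measure the spread between animals, and the call rests on 1 vehicle pool. Without TA_6h animal 1, or without TA_6h animal 2, 0 probe sets were called and the smallest adjusted p was 0.86, and without TA_24h animal 1, 2 were called. By size, 44 probe sets were at least 2-fold higher in both treated animals and 64 at least 2-fold lower, while 538 differed by 2-fold between the 2 animals, and 38 lay beyond both vehicle pools by as much. In animal 1 alone 412 passed and in animal 2 alone 409. Beside Sds, the higher values included A2ml1 at 3.25 ± 0.57, Abcg5, a sterol transporter, at 2.57 ± 1.09, Noct, nocturnin, at 2.38 ± 0.33, the adenosine receptor Adora2b at 2.53 ± 1.04, Onecut1 at 1.85 ± 0.57 and Lox, lysyl oxidase, at 1.61 ± 0.47. The lower values included the repressor Bcl6 at -3.03 ± 1.67, the metallothionein Mt2A at -2.33 ± 0.29, Ildr2 at -2.17 ± 0.35, Serpina7, thyroxine binding globulin, at -1.92 ± 0.33, Lpl, lipoprotein lipase, at -1.56 ± 0.61 and Ppargc1a at -0.98 ± 0.15, with -0.03 on its other probe set. Against the vehicle pool of 6 h the direction turned for Bcl6, at 7.37 there with a TA mean of 7.94, and for Onecut1, at 11.78 there with a TA mean of 10.25. Ildr2 and Abcg5 were at 6.42 and 7.26 in that pool, much nearer to their TA means of 6.09 and 7.66, and A2ml1 and Lox at 3.80 and 7.46, with TA means of 5.49 and 8.52. Noct, Serpina7 and Ppargc1a, at 2.65, 9.44 and 6.60 there, stood further from their TA means of 7.40, 6.51 and 4.42 than in the pool of 24 h. Mt2A, at 8.04 and 8.09 in the animals, was below both vehicle pools, 10.39 at 24 h and 12.98 at 6 h. The retinoic acid hydroxylase Cyp26a1 had 1.28 ± 0.31. Cdkn1a had 0.85 ± 0.17 on the probe set used and -0.79 on its other one. Cytokines and NF-kB targets had a median of 0.01 (adjusted p = 0.95), heat shock proteins 0.05 (adjusted p = 0.42) and p53 targets -0.01 (adjusted p = 0.95). The interferon response had -0.28 with 21 of 28 genes negative, -0.02 in animal 1 and -0.47 in animal 2, and was not called (camera, adjusted p = 0.15). The mean of the cytokine list was -0.02 and that of the p53 list 0.06, each opposite in sign to its median, and the sign of the p53 median turned when arrays were rescaled.

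**Figure D2:**
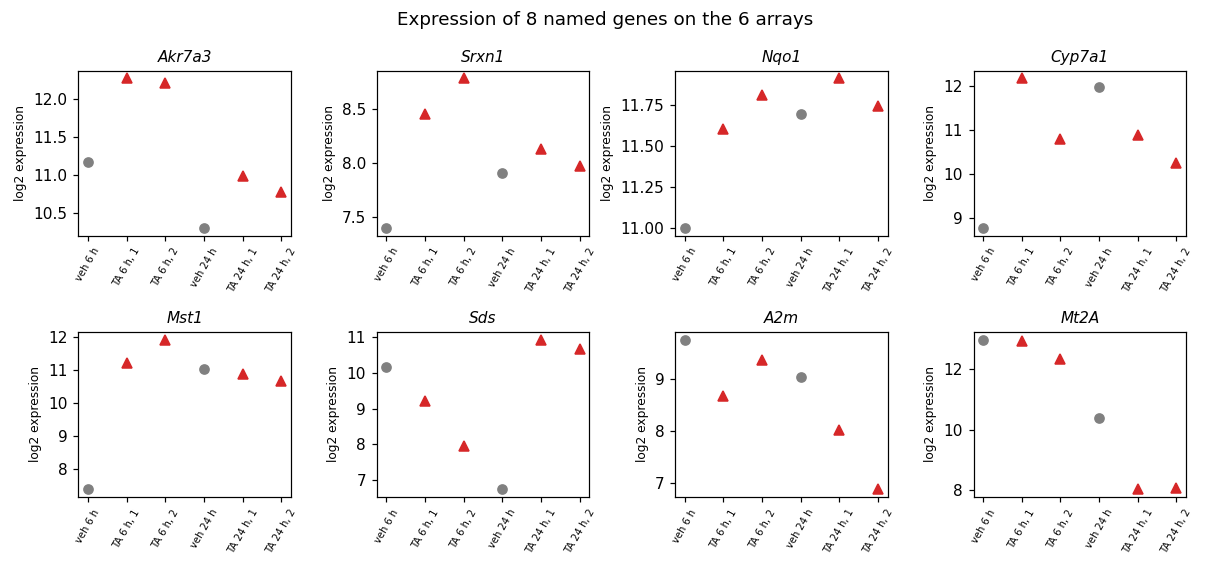
Log2 expression (y axis, a separate scale for each gene) of 8 named genes on the 6 arrays (x axis), with grey circles for vehicle pools and red triangles for single treated animals. Mst1 is at 7.39 in the vehicle pool of 6 h and between 10.68 and 11.92 on the other arrays, and Mt2A is at 8.04 and 8.09 in the TA animals of 24 h.

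Averaged over both times, the difference of TA from vehicle called 9 of the 33 lists, 8 of them upward relative to the other genes. The urea cycle list had a median of 0.16 (camera, adjusted p = 2.5e-06), the Nrf2 list 0.13 (adjusted p = 7.1e-05), the transferases 0.09 (adjusted p = 0.0018) and urate and organic anion handling 0.12 (adjusted p = 0.022). Acute phase proteins had -0.10 (adjusted p = 0.0015). With an estimated correlation the smallest adjusted p was 0.67. Med13 was at least 2-fold lower in all 4 treated animals, at -1.45 ± 0.23 (limma, adjusted p = 0.74), on the probe set used. Its other probe set had 0.0046 at 6 h and 0.02 at 24 h. Of single probe sets, limma called the unnamed one of 24 h again (-4.00, adjusted p = 0.029, again from values at the floor). An unadjusted p under 0.05 was seen for 1196, of which 332 were higher and 864 lower. The call of the unnamed probe set was lost without any 1 of the 4 treated animals. The 6 h and 24 h differences, which share no array, correlated at 0.07 across probe sets, which are not independent replicates.

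From 6 h to 24 h, 262 probe sets were at least 2-fold higher in the means of TA and 305 lower, of which 87 and 98 were also 2-fold apart that way between the vehicle pools. Of the 33 lists, 7 were called from 6 h to 24 h in TA. Cell cycle genes rose as a list, by a median of 0.62 over 34 genes, 20 of them called when adjusted over the list alone (camera, adjusted p = 4.5e-08; adjusted p = 0.67 with an estimated correlation), and by 0.59 between the vehicle pools. Aurka and Cdk1, mitotic kinases, had 1.96 ± 0.15 and 1.25 ± 0.16 in TA. Heat shock proteins rose by a median of 0.34 (adjusted p = 0.00022), against 0.25 between the vehicle pools (adjusted p = 0.67 with an estimated correlation). Among clock genes, Nr1d1 had -5.05 ± 0.22 in TA and -5.54 in vehicle, Cry1 4.33 ± 0.28 and 3.35, and Per2 3.60 ± 0.16 and 2.76, with 8 of 17 called when adjusted over the list alone and camera's test of the list not passed (adjusted p = 0.082). Nr1d1 at 24 h lay at the floor of the values, from 1.96 to 1.97, so that its difference is compressed. Genes of bile acid synthesis and hepatobiliary transport fell as a list, by a median of -0.30 with 17 of 20 lower and 4 called when adjusted over the list alone (adjusted p = 0.0042; adjusted p = 0.67 with an estimated correlation), against -0.39 in vehicle. The urea cycle list had 0.13 in TA (adjusted p = 0.037; adjusted p = 0.67 with an estimated correlation) and -0.16 in vehicle, and lost its call without TA_6h animal 1 (adjusted p = 0.069) and without TA_24h animal 2 (adjusted p = 0.14). Stellate markers had -0.78 in TA (adjusted p = 0.00055; adjusted p = 0.67 with an estimated correlation) and -0.13 in vehicle. Markers of endothelium and of macrophages also fell as lists, with medians of -0.24 (adjusted p = 0.019; adjusted p = 0.67 with an estimated correlation) and -0.26 (adjusted p = 0.026; adjusted p = 0.73 with an estimated correlation), against -0.14 and -0.04 in vehicle. At 6 h, animal 1 stood at 0.38 from vehicle in the stellate list and 0.27 in the macrophage list, and animal 2 at -0.09 and 0.04. Without TA_6h animal 1 the change from 6 h to 24 h was -0.49 in the stellate list, still called (adjusted p = 0.030), and -0.10 in the macrophage list, whose call was lost (adjusted p = 0.29). Without TA_24h animal 1 the macrophage and endothelial calls were lost (-0.18, adjusted p = 0.18, and -0.11, adjusted p = 0.23). Without TA_6h animal 2 the macrophage median was -0.44, and without TA_24h animal 2 the endothelial median was -0.45, both still called. Cholangiocyte markers, 4 genes, had -0.54 and were not called (adjusted p = 0.14). Over all genes limma called 0 probe sets between the times (smallest adjusted p = 0.14), and 2760 had an unadjusted p under 0.05. Time of day, the number of doses and time since dosing differ together between these groups.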

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

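Results whose TA effect differed between 6 h and 24 h, by the test of the difference itself, are given here. Nrf2 targets and RT1-Bb did not enter by that test. RT1-Bb is given because its probe sets went opposite ways at 24 h (-4.74 and 1.29). The tests of an RT1 allele, of antigen-presenting cells and of the share of non-hepatocyte cells were chosen only after the result was seen. Those against the vehicle pool of the other time and within a fluidics run were added after seeing the data. Their bounds were set before their own result was seen. Leaving out animals in these list tests was added as well. Bootstrap intervals below resample the genes of a list on the same arrays, so they do not measure the spread between animals.

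A probe set with no gene symbol here had a difference of TA effects (24 h minus 6 h) of -7.21 (limma, adjusted p = 0.042). It was at 9.84 in the vehicle pool of 24 h and at most 2.61 on the other arrays, where values are compressed, so that the test's error does not measure the spread between animals. The call was lost without any 1 of the 4 treated animals.

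Urea cycle and amino acid catabolism genes had a median difference of TA effects of 0.29 over 25 genes (camera, adjusted p = 0.00038; adjusted p = 0.83 with an estimated correlation). Sds had -1.57 ± 0.59 at 6 h and 4.08 ± 0.59 at 24 h.

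Stellate cell and fibroblast markers had a median of 0.13 at 6 h (0.38 in animal 1 and -0.09 in animal 2) and -0.35 at 24 h. The median difference of TA effects was -0.53 over 15 genes (camera, adjusted p = 0.00038; adjusted p = 0.83 with an estimated correlation), and -0.26 without TA_6h animal 1 (adjusted p = 0.045). Whether the vehicle pool of 24 h stood apart cannot be told. Against the pool of 6 h the median at 24 h was -0.75, with a bootstrap 95% interval from -1.13 to -0.12. The upper end lay only just beyond the bound set, and the list test lost its call there (camera, adjusted p = 0.064). That comparison also differs in time of day and number of doses, so it cannot separate the pool from time. A lower share of all non-hepatocyte cells by a like amount is argued against for these arrays only. The median of endothelial and macrophage markers lay 0.27 above that of stellate markers, with an interval over genes from 0.16 to 0.59. The lower end lay only just above the bound of 0.15, and the spread between animals is not in it. Endothelial markers alone had a median of -0.13 at 24 h, with 11 of 14 genes negative. Pooling them with the macrophage markers cannot exclude an unequal fall over cell types. A vehicle pool standing apart, a change within stellate cells or in their share alone, an unequal fall over cell types, and differences between single animals stay open.

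Nrf2 targets at 6 h were weighed because they led that comparison; the difference of their effects between times was not called. Against the vehicle pool of 24 h their median was 0.25 (interval from 0.08 to 0.58), against 0.31 with their own pool. Within the first fluidics run, where only animal 1 can be compared, it was 0.19 (interval from -0.13 to 0.51). Both intervals reach too low to exclude either, so that a vehicle pool standing apart and a difference between runs cannot be told apart from an effect of TA with 1 pool per time and 1 treated animal in the first run.

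The RT1-Bb gene, an MHC class II chain, had 1 probe set at 7.22 in the vehicle pool of 24 h and at most 2.55 elsewhere, and another at 8.13 there and at least 9.30 elsewhere. More antigen-presenting cells in that pool are argued against: macrophage and lymphocyte markers stood a median of -0.057 from the other arrays (interval from -0.18 to -0.03). Another RT1 allele may be present in a pooled rat, since that pool stood 2-fold apart at 3 of 27 RT1 probe sets and at 29 of 18598 others (Fisher's exact test, two-sided p = 1.3e-05). However, 2 of the 3 are the probe sets that prompted the test, and without them it was 1 of 25 (Fisher's exact test, p = 0.040), too few to see both signs, so that the allele stays open.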

How the results depend on the processing

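The fluidics run, the vehicle pool of the other time, the 2 reduced lists, the replicate block in the list tests and leaving out animals in the list tests between times were chosen after seeing the data. With 1 vehicle array per time, a vehicle pool could be left out only in the additive model, which then repeats the test of the other time alone and does not test the mean, and a lone treated array was assumed to vary like the other treated pair. Calls of probe sets at 6 h were 0 under every setting run except 1 against the vehicle pool of the other time, which is the unnamed probe set called at 24 h. The single call of 24 h, of the mean and of the difference of effects became 0, 0 and 0 with the stricter filter, which removes that probe set, and likewise with the replicate block and with the fluidics run as a block. With an intensity trend the counts were 2 at 24 h and 2 for the mean. With both vehicle pools as 1 control group 24 h gave 0, the additive model gave 0 for the mean, and against the vehicle pool of the other time 24 h gave 0. Leaving out arrays in turn gave 0 to 2 calls at 24 h, 0 to 1 for the mean and 0 for the difference.

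The replicate numbers were not a pairing: the animals differ, and the differences between animals 1 and 2 at 6 h and at 24 h correlated at -0.08 across probe sets. The block, with 1 residual degree of freedom, gave 0 calls at both times, with a smallest adjusted p of 0.057 at 24 h, and 8 and 6 lists were called, without Nrf2 targets at 24 h (adjusted p = 0.36) and PPAR alpha targets at 6 h (adjusted p = 0.21).

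Lists called were 6 at each time and became 0 at 6 h and 0 at 24 h with an estimated correlation, and 0 and 0 with fry. Leaving out arrays gave 2 to 7 lists at 6 h. With independent simulated genes, the estimated correlation called a shifted list in 0 of 20 runs as well. Fry called it in 1 of 20 at a shift of 0.2 and in 5 of 20 at 0.4. A call lost under either test therefore cannot decide about that list. In the data, estimated correlations of the lists called at 6 h went from 0.06 (cholesterol synthesis) to 0.56 (MHC), with 0.14 for Nrf2 targets, above the preset 0.01. Those of 24 h went from -0.0076 (urea cycle) to 0.14 (Nrf2 targets). The urea cycle list lost its call too, so a correlation above the preset does not account for every loss. How often the preset test calls unshifted lists of correlated genes was not tested, so the simulation does not speak for its p-values. The cell cycle median at 6 h turned to -0.24 with both vehicle pools as 1 control group and to -0.54 against the vehicle pool of the other time; the cause was not tested. Without the genes of the urea cycle list the periportal median turned to -0.034, on 6 genes. Of 218 tests of called lists under alternatives, 153 kept the call and its direction, 64 lost the call and 1 was called the other way. These are not independent checks. Leaving out an animal of the other time cannot move the median of a list at 6 h or 24 h. The fluidics run as a block repeats the fit without TA_6h animal 2. The sign of the median differed in 11, of which 10 were not called.

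The counts past 2-fold, 98 and 108, became 265 to 469 at 6 h and 409 to 412 at 24 h with 1 treated animal left out, since 1 animal then has to pass instead of both. Against the vehicle pool of the other time they were 276 and 456; the cause was not tested. Of 189 values of named genes, 51 changed sign against the vehicle pool of the other time and 13 with both pools as 1 control group. Over all settings run for them, 86 of 2079 changed sign and 0 passed the threshold. This total includes the same repeated and unmoved settings, so it does not measure how stable the values are. Rescaling moved the median of all probe sets by at most 0.06. Differences near the floor of the signal are compressed and limit what low probe sets can show.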

Other observations

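The counts of probe sets standing apart on single arrays were chosen after seeing the data, and the other tests before. Among iron and metal genes, Tfrc had 1.37 ± 0.17 at 6 h, with 1.71 on its other probe set, and Hamp -1.91 ± 0.91, whereas at 24 h Mt2A had -2.33 ± 0.29 and Mt1 -1.11 ± 0.51. Tfrc was at 11.83 in the vehicle pool of 24 h, above the treated animals of 6 h, and Hamp was at 11.07 and 12.95 in the TA animals of 24 h. No gene of this list passed limma's test over all probe sets, and Tfrc at 6 h and Mt2A at 24 h were each called when adjusted over the list alone, 1 of 10 genes.

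Genes of urate handling, which TA as a uricosuric drug affects in the kidney, had medians of 0.10 at 6 h (camera, adjusted p = 0.11) and 0.09 at 24 h (adjusted p = 0.28) in liver. Slc17a1, an anion transporter, had 0.69 ± 0.18 and Uox, urate oxidase, 0.25 ± 0.10 at 24 h.

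Arrays differed in how many probe sets stood 2-fold apart from all others: 44 for the vehicle pool of 6 h, 90 and 20 for the TA animals of 6 h, 32 for the vehicle pool of 24 h, and 115 and 70 for the TA animals of 24 h. The 3′ minus 5′ signal of GAPDH, a measure of RNA integrity, lay between 1.82 and 2.26 (log2), highest in TA_6h animal 1, and that of actin between 4.17 and 4.36, with this array at 4.31.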
